A study of Mus musculus with 6 samples.

How the data were processed

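RNA was sequenced from mouse CD4+ T cells of the C57BL/6 strain that had been cultured for 3 days, per the labels' protocols, from naive cells in medium with 10% serum, anti-CD28 at 2 µg/ml, anti-IFN-γ at 10 µg/ml, anti-IL-4 at 5 µg/ml and TGF-β1, IL-6 and IL-23 at 10 ng/ml each. The 6 libraries fell into 2 groups of 3, cultures with CKBA and cultures with DMSO, by their titles. The dose of CKBA was not given in the sources used here. Total RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit, per the labels' protocols. Whether the kit kept strand was not given, so reads of a gene and of an overlapping antisense gene cannot be told apart. The labels name epidermis as source and tissue, and CD4+ T cells as cell type. The culture protocol and the design text describe T cells, and the samples are treated as T cells here.

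The deposited table held estimated counts per gene and library, which the submitters' processing notes tie to RSEM (version not given), with CASAVA 1.8 and the GRCm38 genome build. The aligner and the annotation release were not given. RSEM divides reads that match several genes between them, so values of near-identical copies are uncertain. All deposited expected counts were whole numbers, so rounding changed none of them. The table also held the authors' FPKM per library, used only in an alternative test, and the authors' log2 fold changes, p-values and FDR from edgeR per the submitters' processing notes, used only for a comparison of calls. The authors' FPKM per group were not used, because their weighting was not stated. A second deposited table of pathway annotations held no measurement and was not used here. Of 47725 genes in the count table, 47306 identifiers matched the GENCODE M21 annotation of GRCm38, and 23224 genes had no count in any library. Another 138 rows repeated a symbol and were told apart by identifier.

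Total counts per library lay between 19838347 and 25331863, and the 10 most abundant genes took 5.84% to 7.04% of them. The same fits were tested on simulated data drawn from the means and library sizes of these samples, with 200 genes changed, all at a mean of at least 5 CPM. The oxidative phosphorylation list was also raised by a small amount, and it was called. On 13729 simulated genes, 22 of 50 genes changed 1.5-fold, 45 of 50 changed 2-fold, 50 of 50 changed 4-fold and 47 of 50 changed 8-fold were called, as were 6 of 13493 unchanged genes. With no gene changed, 0 genes and 0 of 30 lists were called. The genes were drawn independently of each other and without differences carried by the replicate number. The simulation is therefore no guide to false list calls in the real libraries. There, the splits into 3 and 3 other than the real one called 5 to 9 lists. Those splits still set unequal numbers of CKBA and DMSO libraries against each other, so the treatment may account for part of these calls.

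The genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion estimates, TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. This left 13928 genes. Expression is given as CPM, counts scaled to library size after TMM, as mean ± SD over 3 libraries, and fold changes as log2 of CKBA over DMSO ± SE. Where a group had no count in any library, a bound was computed against a floor of 3 counts over the group, which covers counting error only.

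Before the data were examined, 33 gene lists were fixed: TH17, IL-6 and STAT3, Treg, TH1, TH2, TGF-β response, naive and memory, activation, stress response (integrated stress response and unfolded protein response), serine and one-carbon metabolism, ribosomal proteins, cell cycle, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, hypoxia, fatty acid synthesis, fatty acid oxidation, cholesterol synthesis, LXR targets, leukotriene and prostaglandin pathway, NRF2 targets, heat shock, p53 and apoptosis, NF-κB targets, interferon, CD8 and NK cells, B cells, myeloid cells, keratinocytes, fibroblasts, erythroid cells and non-polyadenylated histones. Of 649 listed symbols, 7 were not matched. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 30 lists, and 3 lists were too small. Camera with an estimated correlation and fry were alternatives. Members were counted as rising or falling by the gene test, over all genes and adjusted over the list alone.

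The rule for named genes was also fixed then. It took the 10 largest changes in each direction among called genes with at least 5 CPM in the higher group, a curated symbol and no overlap between the groups. It added up to 4 members of each list with the smallest adjusted p, or the 2 most abundant where fewer passed, and genes chosen for the question, among them Il17a, Il17f, Il22, Foxp3 and Acaca. This gave 132 genes, 117 of them past the threshold. Genes outside the rule are marked where they are named, and results of some genes within it are not reported here.

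The titles number the replicates 1 to 3 in each group. Deviations from the group means correlated across genes by 0.244, 0.235 and 0.436 between libraries of the same number. All 3 values were above the 0.1 set as the limit for pairing, so a fit with the replicate number as a block is printed where it changes a call. The pairing comes from the numbers in the titles and this check alone. Deviations from a group mean sum to 0 over its 3 libraries, so the 3 values are not separate checks. DMSO replicate 1 and CKBA replicate 2 also correlated by 0.232, and DMSO replicate 2 and CKBA replicate 1 by 0.244. The check therefore does not tell replicate numbers 1 and 2 apart.

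Other settings fixed before the data were seen were other size factors, other low-count filters, DESeq2 1.42.0, limma-voom, the edgeR exact test, a minimum fold, a test on FPKM with a pseudocount of 1, the block, and each library left out. Chosen after the data were seen were leaving out replicate 3 of both groups, a covariate for replicate 3, summing replicates 1 and 2 of each group, and removing each library's smooth trend with transcript length or GC content, from GENCODE M21 transcripts.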

Results

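Gene expression was measured by RNA-seq in mouse naive CD4+ T cells cultured for 3 days under conditions that drive the TH17 fate, a helper T cell state marked by the cytokines IL-17A and IL-17F. The cultures held CKBA, a derivative of acetyl-keto-boswellic acid, a triterpenoid of frankincense resin, or the vehicle DMSO. Each group had 3 libraries. Total counts were 19838347, 20580744 and 20687649 in DMSO replicates 1, 2 and 3, and 20659873, 20622192 and 25331863 in CKBA replicates 1, 2 and 3. The labels give epidermis as the tissue but T cells as the cell type. Cd4, chosen after its values were seen, stood at 474 ± 23.2 CPM with DMSO and 363 ± 87.6 CPM with CKBA (mean ± SD, n = 3 each), while 6 of 20 keratinocyte marker genes were abundant enough to test. Nothing in the labels states that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

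The comparison of CKBA with DMSO asks which transcripts differ when the compound is present during polarization. By camera the TH17 list was lower with CKBA, and the lists of the integrated stress and unfolded protein responses and of serine and one-carbon metabolism were higher. With an estimated correlation none of these 3 lists was past the threshold (adjusted p = 0.145, 0.249 and 0.308). Il17a, which encodes IL-17A (ENSMUSG00000025929, GRCm38 chromosome 1, 20730905 to 20734496, plus strand), fell from 139.8 ± 40.2 to 12.1 ± 0.826 CPM, a log2 fold change of -3.53 ± 0.22 (adjusted p = 3.24e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Trib3, a pseudokinase gene switched on by the stress factor ATF4 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032, minus strand), rose from 12.3 ± 1.55 to 108 ± 5.33 CPM, a log2 fold change of 3.13 ± 0.11 (adjusted p = 3.73e-05, same test). Of 13928 genes tested, 1095 were higher and 1286 lower with CKBA, and 264 and 464 of these changed by at least 1 on the log2 scale. In 1092 of the higher and 1272 of the lower genes, the 3 libraries of one group lay on one side of the other 3. Of all tested genes 36.6% were separated in this way, against 10% by chance. With the replicate number as a block, 1922 genes were higher and 2009 lower.

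**Figure D1:**
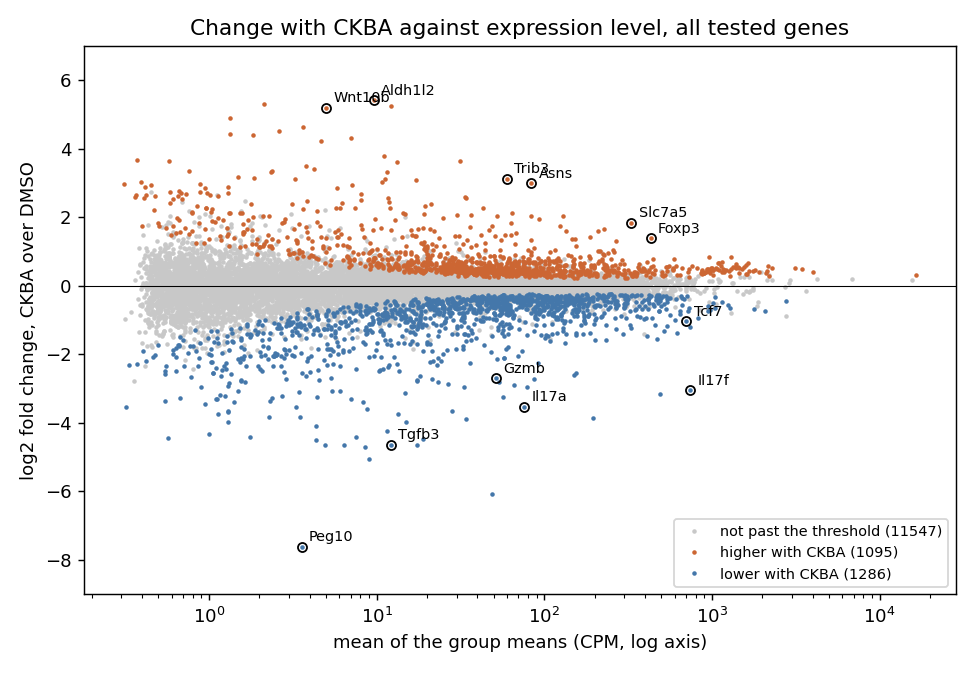
Log2 fold change of CKBA over DMSO against the mean of both group means in CPM on a log axis, 1 point per tested gene, with genes past the threshold coloured by direction and 12 named genes circled. The 1095 higher and 1286 lower genes lie across the range of expression, and Ly6g, with no count in any CKBA library, falls outside the axis.

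The libraries were unevenly spaced. Within each group, replicates 1 and 2 lay close together, with a chi-square per gene of 3.35 for DMSO and 2.86 for CKBA, where sampling alone gives about 1, and replicate 3 stood apart, with 35.03 to 37.99 against its group's other libraries. On the first principal component, with 56.6% of the variance, DMSO replicates 1 and 2 lay at -45.2 and -45.7, DMSO replicate 3 at -15.7 and the CKBA libraries at 34.6 to 37.0. On the second, with 25.25% of the variance, replicate 3 lay at -33.3 with DMSO and -34.8 with CKBA. The other libraries lay at 10.5 to 25.3 there. The counts depended on which libraries entered: 269 higher and 417 lower without DMSO replicate 1, 251 and 390 without DMSO replicate 2, 348 and 455 without CKBA replicate 1, 347 and 444 without CKBA replicate 2, and 1961 and 2014 without CKBA replicate 3. With replicates 1 and 2 of each group summed to 1 library, an alternative chosen after seeing the data, 56 genes were higher and 54 lower. If replicates 1 and 2 of a group were repeat libraries of 1 culture, which the labels do not say, that fit would be the relevant one, and 110 of the 2381 calls would remain. Without replicate 3 of either group, also chosen then, 3660 were higher and 3728 lower. Of the 117 named genes past the threshold, 59 stayed past it whichever library was left out, and 89 lost their call when replicates 1 and 2 were summed. Il17a, Ahr, Tcf7, Gzmb, Trib3, Asns, Phgdh and Slc7a5 were among the genes still called in that fit, with adjusted p of 0.0256, 0.0354, 0.0482, 0.00711, 0.00711, 0.0376, 0.0461 and 0.0387 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

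**Figure D2:**
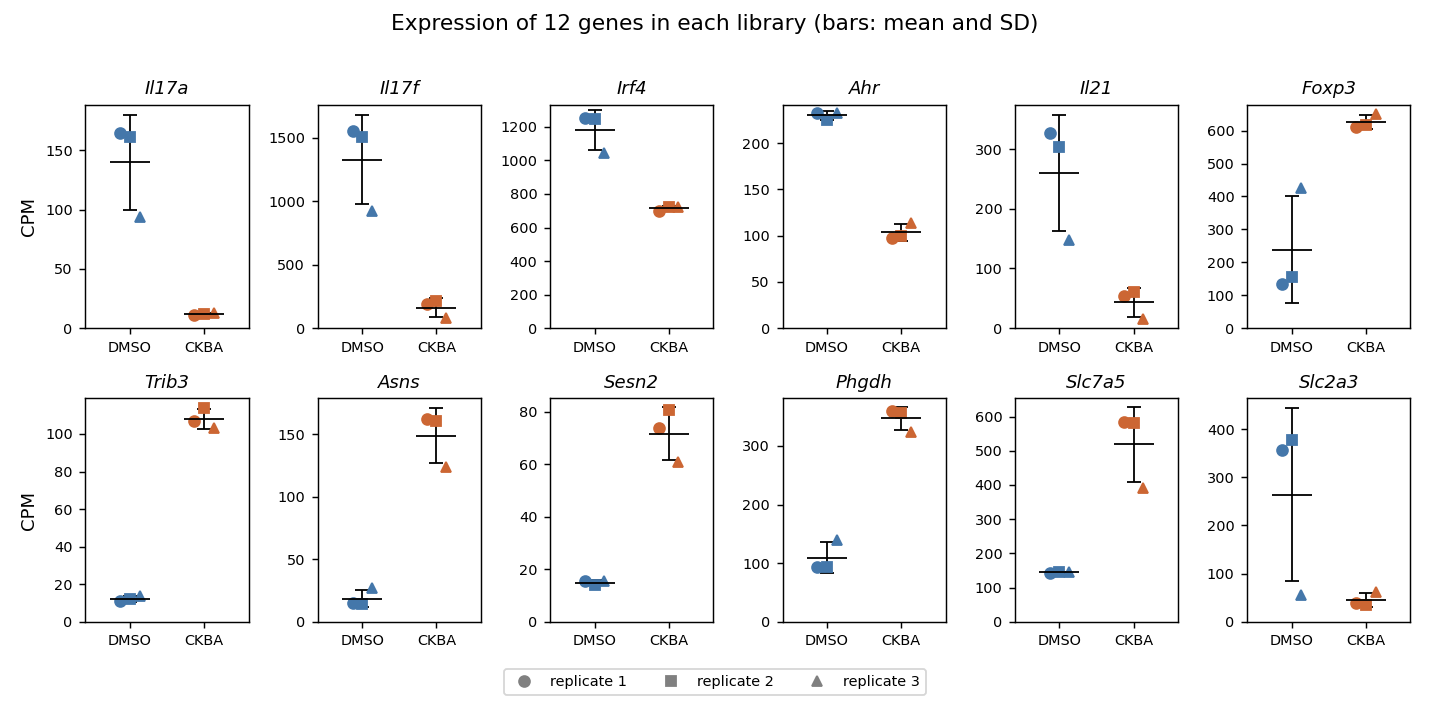
Expression in CPM of 12 named genes in each library, with DMSO in blue, CKBA in orange, 1 symbol per replicate, and black bars for the mean and SD of 3 libraries. Il17a, Irf4 and Ahr are lower and Trib3, Asns and Sesn2 higher in every CKBA library, while Slc2a3 in DMSO replicate 3 lies with the CKBA libraries.

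TH17 genes fell as a group. Of 24 tested members, 16 fell and 3 rose, also when adjusted over the list alone, with a median log2 fold change of -0.99. The list was lower by camera (adjusted p = 3.65e-07), and the adjusted p = 0.145 with an estimated correlation. The estimated correlation was 0.0064, below the preset 0.01, so correlation between members does not account for that loss. Il17f, which encodes IL-17F, fell from 1328 ± 352 to 161 ± 72.5 CPM (log2 fold change -3.04 ± 0.38), and Ahr, the aryl hydrocarbon receptor, from 230.1 ± 4.63 to 103.6 ± 9.14 CPM (-1.15 ± 0.08). Tgfb3 and Irf4 fell, with log2 fold changes of -4.64 and -0.73. For these 4 genes the adjusted p were 0.0025, 4.42e-04, 0.00619 and 0.00244 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Tgfb3 call was lost without CKBA replicate 1, 2 or 3, with an adjusted p of up to 0.0615 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 members that rose, named after their values were seen, were Csf2, which encodes GM-CSF, with a log2 fold change of 3.11, the chemokine gene Ccl20 with 0.52 and Podxl with 1.46. Il22 did not pass the test, at 2.66 ± 2.5 CPM with DMSO and 3.78 ± 6.2 CPM with CKBA. Its estimate turned from 0.53 to -0.40 with the replicate block and to -3.72 without CKBA replicate 3, where it passed (adjusted p = 0.0487, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fewer TH17 members fell without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, at 10, 10, 9 and 10, and 1, 0, 1 and 1 rose. Only 3 fell and 0 rose with replicates 1 and 2 summed.

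Genes downstream of IL-6 and STAT3, the pathway that induces the TH17 fate, were also lower. Of 14 members, 7 fell and 0 rose (7 and 1 adjusted over the list alone), with a median of -0.26. Il21, Socs3, Bcl6 and Bcl3 fell, with log2 fold changes of -2.60, -0.94, -0.80 and -0.44 and adjusted p of 0.013, 0.00358, 0.00473 and 0.0142 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Camera gave an adjusted p = 0.0146, and the adjusted p = 0.249 with an estimated correlation. Without DMSO replicate 3 the camera call was lost (adjusted p = 0.103). It was also lost with the GC trend removed (0.0579), with the replicate block and the length trend removed (0.0519), and with the block and the GC trend removed (0.112), alternatives chosen after seeing the data. In these 3 fits the median was -0.26, -0.24 and -0.25 with an SD of 0.80, 0.82 and 0.83 between members, against -0.26 and 0.78 before. Only 3, 2, 2 and 3 members fell without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2, and the Il21 call was lost in each of those 4 fits (adjusted p of up to 0.0892 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Bcl3 call was lost without DMSO replicate 2 or CKBA replicate 1, with an adjusted p of up to 0.0809 in that test. With the replicate block, 7 members fell and 3 rose, and 2 rose without DMSO replicate 3. In the fit with replicates 1 and 2 summed, 0 fell.

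The integrated stress response and unfolded protein response list was higher with CKBA. Of 24 members, 10 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.17 and a mean of 0.92, and by camera the adjusted p = 4.57e-05. The adjusted p = 0.249 with an estimated correlation. The median was 0.08 without CKBA replicate 1, 0.27 without CKBA replicate 3 and 0.11 with replicates 1 and 2 summed, where 3 members rose. Asns, asparagine synthetase, rose from 18.6 ± 6.94 to 148.8 ± 21.8 CPM (log2 fold change 3.00 ± 0.25), and Sesn2, which encodes sestrin 2, from 14.9 ± 0.874 to 71.5 ± 10.1 CPM (2.26 ± 0.12). Herpud1, a gene of endoplasmic reticulum protein degradation, rose by 0.98. The adjusted p of these 3 genes were 5.04e-04, 1.98e-04 and 9.4e-04 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The chaperone genes Hspa5 at 0.03, Hsp90b1 at -0.10, Calr at 0.07 and Pdia6 at -0.04, named after their values were seen, did not pass the test.

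Serine and one-carbon metabolism genes rose with them. Of 15 members, 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.67, and by camera the adjusted p = 8.06e-09. The adjusted p = 0.308 with an estimated correlation. Only 4 members rose with replicates 1 and 2 summed. Phgdh, the first enzyme of serine synthesis, rose from 109.1 ± 26.5 to 346.9 ± 19.97 CPM (1.67 ± 0.16), Mthfd2, a mitochondrial folate enzyme, from 57.2 ± 13.3 to 191 ± 6.32 CPM (1.74 ± 0.15), and Slc1a4, a carrier of serine and other neutral amino acids, from 9.65 ± 2.98 to 58.0 ± 6.88 CPM (2.58 ± 0.21). Aldh1l2, a mitochondrial folate enzyme, had the largest rise of the list, from 0.432 ± 0.36 to 18.9 ± 3.66 CPM (5.41 ± 0.42). The adjusted p were 8.71e-04, 6.1e-04, 5.04e-04 and 4.87e-04 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

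**Figure D3:**
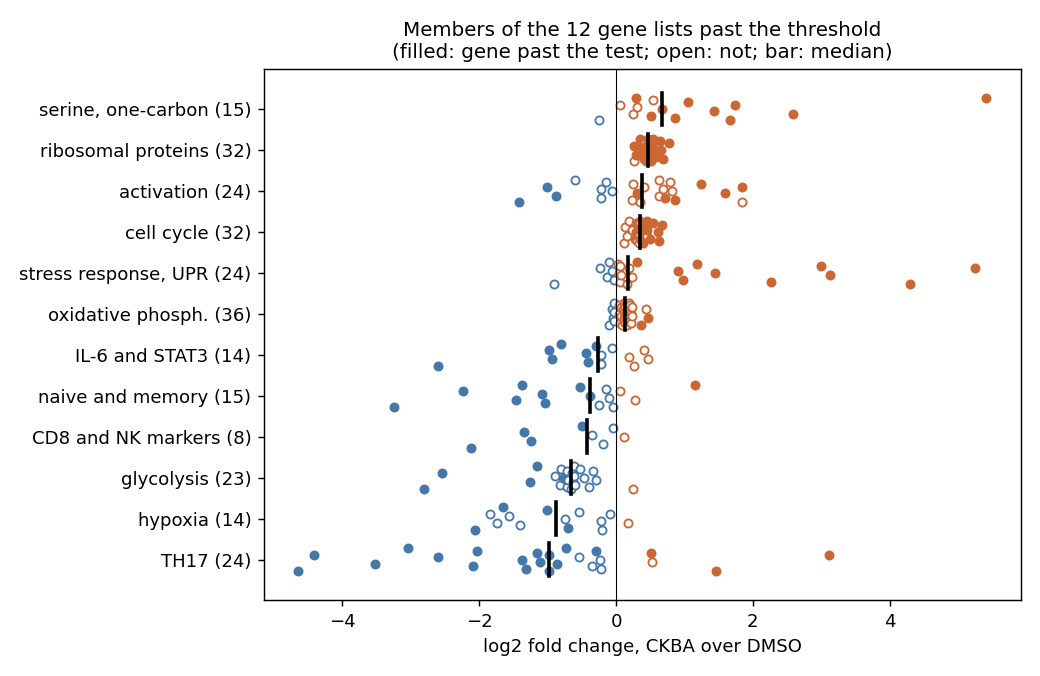
Log2 fold change of CKBA over DMSO of each tested member of the 12 gene lists past the threshold, 1 point per gene, filled where the gene passed the test and open where not, with a black bar at each median and the number of members beside each name. The ribosomal protein list has all 32 members above 0, and the TH17 list has its median at -0.99.

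Ribosomal protein genes rose by small and even amounts. Of 32 members, 30 rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.47 and an SD of 0.12 between members. Rps19 rose by 0.78, Rps24 by 0.65, Rps18 by 0.53 and Rpl4 by 0.52, with adjusted p of 0.00257, 0.00189, 0.00267 and 0.00276 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list was higher by camera (adjusted p = 7.64e-18), and the adjusted p = 0.308 with an estimated correlation. Without CKBA replicate 3 it passed with an estimated correlation too (adjusted p = 0.0469, camera). These genes have many processed pseudogenes that can share reads with them, so single values are uncertain. The number that rose was 11 without DMSO replicate 1, 11 without DMSO replicate 2, 17 without CKBA replicate 1, 16 without CKBA replicate 2 and 0 with replicates 1 and 2 summed.

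Cell cycle genes were also higher as a list, but less so in replicate 3. Of 32 members, 20 rose and 0 fell (27 and 0 adjusted over the list alone), with a median of 0.35. Their mean difference on the log2 scale was 0.51 and 0.49 within replicate pairs 1 and 2 and 0.10 within pair 3. Foxm1, a transcription factor of the G2 phase, rose by 0.62, the mitotic kinesin gene Kif11 by 0.62, the replication helicase gene Mcm5 by 0.54 and the kinesin gene Kif23 by 0.46, with adjusted p of 0.00832, 0.0119, 0.00956 and 0.0108 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As a list they were higher by camera (adjusted p = 4.85e-11), and the adjusted p = 0.446 with an estimated correlation. Single genes depended on the libraries: 0 members rose with replicates 1 and 2 summed, and 1, 0, 3 and 1 members rose without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2 (edgeR's quasi-likelihood test). The calls of Foxm1 (without DMSO replicate 2), Mcm5 and Kif23 (without DMSO replicate 1, DMSO replicate 2 or CKBA replicate 2) and Kif11 (without these or CKBA replicate 1) were lost, with adjusted p of up to 0.0522, 0.0597, 0.0627 and 0.0646 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Oxidative phosphorylation genes were higher as a list over the groups, but not in CKBA replicate 3, with 2 of 36 members past the test, Cox7c at 0.46 and Ndufs8 at 0.37, 0 members adjusted over the list alone, and a median of 0.13. Relative to the mean of the DMSO group they averaged 0.24, 0.21 and -0.07 in CKBA replicates 1, 2 and 3 on the log2 scale, and the difference within replicate pair 3 was -0.03. The median was 0.07 without CKBA replicate 1 and 0.23 without CKBA replicate 3. Camera gave an adjusted p = 0.0129, and the adjusted p = 0.713 with an estimated correlation. That call was lost without DMSO replicate 3, CKBA replicate 1 or CKBA replicate 2, with adjusted p of 0.0802, 0.171 and 0.0839 by camera, and fry gave 0.353. In alternatives chosen after seeing the data it was lost with replicates 1 and 2 summed (0.101), with the length trend removed (0.241), and with the replicate block and the length trend removed (0.229). In the summed fit the median was 0.085. With the length trend removed it was 0.09 with an SD of 0.12 between members, against 0.13 and 0.13 before, so the call ended with a smaller change and not with a wider spread. Of its members, 0 passed edgeR's test without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, and 18 without CKBA replicate 3.

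Glycolysis and hypoxia genes were lower with CKBA as lists, and DMSO replicate 3 lay at the level of the CKBA libraries. Of 23 glycolysis genes, 5 fell and 0 rose (18 and 1 adjusted over the list alone), with a median of -0.66. Aldoc, an aldolase gene, fell from 93.8 ± 53.2 to 13.3 ± 4.8 CPM, Slc2a3, the glucose transporter GLUT3, from 264 ± 179.8 to 45.1 ± 14.4 CPM, Slc16a3, a lactate exporter, from 376 ± 158 to 157 ± 30.7 CPM, and the phosphofructokinase gene Pfkm from 39.0 ± 5.11 to 22.7 ± 3.2 CPM. Their adjusted p were 0.00981, 0.0287, 0.0307 and 0.00986, and with the replicate block 0.169, 0.297, 0.24 and 0.00897 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 14 hypoxia genes, 4 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.88. P4ha1, Ankrd37, Kdm3a and Ndrg1 fell, with log2 fold changes of -1.01, -1.65, -0.69 and -2.06, adjusted p of 0.0211, 0.0299, 0.0456 and 0.0467, and with the replicate block 0.16, 0.0838, 0.136 and 0.344 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera gave an adjusted p = 3.63e-05 for glycolysis and 0.0114 for hypoxia, and the adjusted p = 0.517 and 0.558 with an estimated correlation. Fry gave adjusted p of 0.148 and 0.317. Relative to the mean of the DMSO group, the glycolysis genes averaged 0.27, 0.34 and -0.62 in DMSO replicates 1, 2 and 3 and -0.81, -0.84 and -0.58 in the CKBA libraries on the log2 scale. In the same order the hypoxia genes averaged 0.45, 0.51 and -0.96, and -0.85, -0.96 and -0.61. In replicate 3 the hypoxia genes were thus higher with CKBA than with DMSO. With the replicate block, 1 glycolysis gene fell and 1 rose, and 0 hypoxia genes changed. Without DMSO replicate 3, 20 glycolysis and 10 hypoxia genes fell. Without replicate 3 of either group the glycolysis median was -1.01. At most 2 glycolysis genes and 1 hypoxia gene fell without any 1 of the other 5 libraries, and Slc2a3, Slc16a3, P4ha1, Ankrd37, Kdm3a and Ndrg1 were called in 1 of these 6 fits only, that without DMSO replicate 3. With replicates 1 and 2 summed, 0 members of either list fell, and the hypoxia call was lost (camera, adjusted p = 0.0565). The calls of Aldoc (without DMSO replicate 1, CKBA replicate 1, CKBA replicate 2 or CKBA replicate 3) and Pfkm (without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2) were lost, with adjusted p of up to 0.0779 and 0.0557 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

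**Figure D4:**
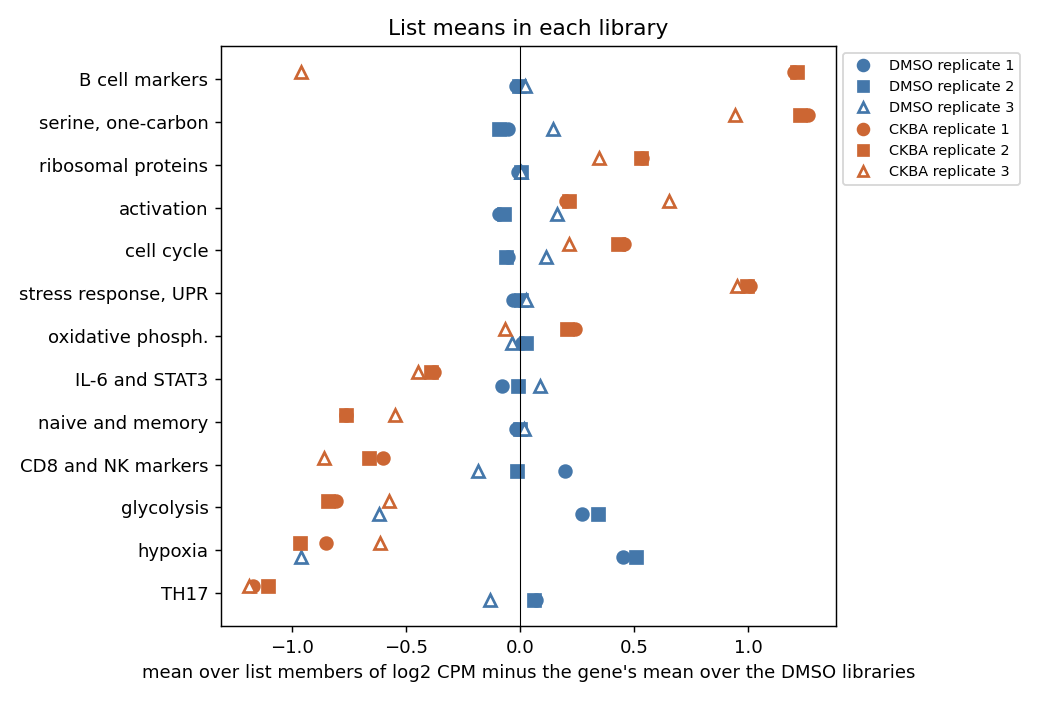
Mean over the members of a list of log2 CPM, relative to each gene's mean over the DMSO libraries, in each library, for the 12 lists past the threshold and the B cell list, with DMSO in blue, CKBA in orange and open triangles for replicate 3. DMSO replicate 3 lies at -0.62 for glycolysis and -0.96 for hypoxia, among the CKBA libraries, but at 0.03 for the stress response and -0.13 for TH17 genes.

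Genes of naive and memory T cells were lower. Of 15 members, 8 fell and 1 rose, also when adjusted over the list alone, with a median of -0.38. Tcf7, which encodes the transcription factor TCF-1, fell from 947 ± 41.4 to 462 ± 41.4 CPM (log2 fold change -1.04 ± 0.09), S1pr1, a receptor for exit from lymph nodes, from 238 ± 7.17 to 112.7 ± 12.6 CPM (-1.08 ± 0.09), and Il7r from 150.6 ± 30.2 to 31.9 ± 8.21 CPM (-2.24 ± 0.21). Their adjusted p were 5.63e-04, 6.05e-04 and 8.74e-04 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list was lower by camera (adjusted p = 2.96e-04), and the adjusted p = 0.249 with an estimated correlation. The member that rose was Id3, with a log2 fold change of 1.16, named after its values were seen. With the replicate block 2 members rose, while without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2 0 rose. Only 4 fell and 0 rose with replicates 1 and 2 summed.

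Activation genes were higher as a list but moved both ways. Of 24 members, 6 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.38. Slc7a5, which encodes the amino acid transporter LAT1, rose from 144 ± 2.07 to 518 ± 110.2 CPM. Slc3a2, which encodes its partner chain, rose from 103.8 ± 1.77 to 313 ± 45.3 CPM. Lag3, an inhibitory receptor gene, and Fosl2 fell, with log2 fold changes of -0.88 and -1.42. The adjusted p of these 4 genes were 5.04e-04, 4.24e-04, 8.71e-04 and 0.00317 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera gave an adjusted p = 0.0486, and the adjusted p = 0.466 with an estimated correlation. The camera call was lost without DMSO replicate 1 (adjusted p = 0.0694) and without CKBA replicate 3 (0.179), and fry gave 0.0669. With the replicate block 15 members rose and 2 fell, without DMSO replicate 3 13 rose, and without DMSO replicate 2 3 rose. Only 2 rose and 1 fell with replicates 1 and 2 summed. The median was 0.75 without DMSO replicate 3 and 0.155 without CKBA replicate 3, and the list averaged 0.20, 0.22 and 0.65 in CKBA replicates 1, 2 and 3 relative to the mean of the DMSO group on the log2 scale.

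Markers of CD8 T cells and NK cells were lower. Of 13 members 8 were tested, of which 4 fell and 0 rose, also when adjusted over the list alone, with a median of -0.43. Gzma, which encodes granzyme A, fell from 84.8 ± 15.3 to 19.4 ± 5.4 CPM (-2.12 ± 0.21), Klrd1, an NK receptor gene, from 86.3 ± 2.54 to 36.5 ± 9.13 CPM (-1.25 ± 0.17), Prf1, perforin, from 22.8 ± 10.1 to 8.94 ± 2.35 CPM (-1.35 ± 0.35) and Cd8a from 28.2 ± 3.74 to 19.9 ± 1.97 CPM (-0.50 ± 0.13). Their adjusted p were 0.00104, 0.00371, 0.0365 and 0.035 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera gave an adjusted p = 0.0127, and the adjusted p = 0.249 with an estimated correlation. The camera call was lost without a low-count filter (adjusted p = 0.22). Without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, 2 members fell, and 1 fell with replicates 1 and 2 summed. The Prf1 call was lost without any library but DMSO replicate 3 (adjusted p of up to 0.136), and the Cd8a call without any library but CKBA replicate 3 (up to 0.137), both in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

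Genes of the other helper T cell fates moved both ways, and none of their lists was past the threshold by camera. Of 18 Treg genes, 5 rose and 3 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.362). Nrp1 rose by 1.48 on the log2 scale, Gpr83 rose by 2.03, and Ctla4, an inhibitory receptor gene that is also in the TGF-β list, fell by 1.56. Foxp3, the Treg master regulator, rose from 238 ± 163.1 to 626 ± 21.4 CPM (log2 fold change 1.39 ± 0.40, adjusted p = 0.0472), but not with the replicate block (0.112), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Foxp3 stood at 135, 154 and 426 CPM in DMSO replicates 1, 2 and 3, and its log2 fold change was 2.12 without DMSO replicate 3. Foxp3 and Gpr83 kept their calls in 1 of the 6 fits without 1 library, that without DMSO replicate 3. Of 17 TH1 genes, 4 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.868). Gzmb, granzyme B, fell from 89.1 ± 15.6 to 13.8 ± 0.997 CPM and Ifng, interferon gamma, rose from 5.06 ± 0.197 to 16.2 ± 5.27 CPM, with adjusted p of 1.96e-04 and 0.00484 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 12 TH2 genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.283), among them Il3 with a rise of 3.17 and Il4ra, which fell by 1.16. Of 18 TGF-β response genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.393), with Smad6 at 1.31. Without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2, the members that rose were 1, 2, 2 and 2 for Treg, 1, 1, 1 and 1 for TH1, 1, 1, 2 and 2 for TH2, and 1, 1, 2 and 1 for TGF-β. In these fits 1 Treg gene fell, and 1, 1, 1 and 2 TH2 genes. Of the Treg genes, 8 rose without DMSO replicate 3, and 3 rose and 5 fell without CKBA replicate 3. With the block, 5 TGF-β response genes fell. With replicates 1 and 2 summed, 1 Treg gene rose, 2 TH1 genes fell, and 0 TH2 or TGF-β response genes passed. The TH1 list had a median of 0.12 and a mean of -0.08, and the TGF-β list 0.11 and -0.02. Both medians were unsteady: that of TH1 was 0.25 with the block, 0.34 without DMSO replicate 2, 0.24 without CKBA replicate 2 and 0.01 without DMSO replicate 3, and that of TGF-β 0.06 without DMSO replicate 1, 0.18 without DMSO replicate 3 and 0.04 without CKBA replicate 3.

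None of the lists of lipid metabolism was past the threshold by camera. Acaca, acetyl-CoA carboxylase 1, stood at 137.6 ± 2.57 CPM with DMSO and 141 ± 7.54 CPM with CKBA, a log2 fold change of 0.04 ± 0.07 (adjusted p = 0.763, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 22 fatty acid synthesis genes, 3 fell and 0 rose (3 and 1 adjusted over the list alone): Elovl6, a fatty acid elongase, at -0.97, the fatty acid synthase gene Fasn at -0.30 and Acss2 at -0.56. With the replicate block 8 fell and 1 rose. The Fasn and Acss2 calls were lost without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, and that of Acss2 also without DMSO replicate 3, with adjusted p of up to 0.2 and 0.157 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 25 cholesterol synthesis genes, 0 passed edgeR's test over all genes or adjusted over the list alone, and 2 rose and 4 fell with the replicate block. Srebf2 stood at 0.02 ± 0.09. Of 22 fatty acid oxidation genes, 3 rose and 1 fell (3 and 4 adjusted over the list alone), and 3 rose and 6 fell with the replicate block. Of 10 LXR targets, Arl4c fell by 0.56 and 0 rose (1 and 0 adjusted over the list alone), and 4 fell with the block. Without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2, only 1, 1, 1 and 1 fatty acid synthesis genes fell, and 0 fatty acid oxidation genes rose or fell. Fatty acid synthesis had 5 falls without DMSO replicate 3 and 5 without CKBA replicate 3, and fatty acid oxidation 3 and 4. Cholesterol synthesis had 2 rises and 1 fall without DMSO replicate 3, and 5 rises without CKBA replicate 3. The Arl4c call was lost without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, with an adjusted p of up to 0.0939 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the LXR targets, 3 fell without DMSO replicate 3 and 2 without CKBA replicate 3. Camera gave adjusted p of 0.294 for fatty acid synthesis, 0.651 for cholesterol synthesis, 0.376 for fatty acid oxidation and 0.101 for LXR targets. Of 12 leukotriene and prostaglandin genes, the pathway of the 5-lipoxygenase that boswellic acids are known to inhibit, 5 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.294). The leukotriene receptor genes Ltb4r1, Cysltr1 and Cysltr2 fell, at -3.31, -2.88 and -1.94 (adjusted p of 6.1e-04, 0.0031 and 0.00798, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Cysltr1 did not pass with the replicate block (0.0624). Of this pathway 0 genes rose without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, and 3 without DMSO replicate 3. With replicates 1 and 2 summed, 1 of them fell and 0 rose, and 0 members of the other lipid lists passed.

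The remaining signalling and stress lists were not past the threshold by camera. Of 20 interferon genes, 2 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.335), and of 21 NF-κB targets 5 rose and 3 fell (8 and 3, adjusted p = 0.23), with 10 rising under the replicate block. Gbp2, a guanylate-binding protein gene, fell by 3.15 and Lta, lymphotoxin alpha, rose by 1.32, with adjusted p of 0.0106 and 0.00234 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Gbp2 call was lost without any library but DMSO replicate 3, with an adjusted p of up to 0.0782 in that test. Of 18 p53 and apoptosis genes, 4 rose and 2 fell (7 and 3 adjusted over the list alone, adjusted p = 0.0974), among them Bbc3, which rose by 1.08, and Pmaip1, which fell by 0.95. Of 22 NRF2 targets, 3 rose and 1 fell (3 and 2 adjusted over the list alone, adjusted p = 0.651, median -0.02, mean 0.09), and 5 rose and 3 fell with the block. Of 11 heat shock genes, 2 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.393). Of 13 mitochondrially encoded genes, mt-Atp6, mt-Co3 and mt-Cytb fell, at -0.99, -0.94 and -0.74, and 0 rose, also when adjusted over the list alone. Camera gave that list an adjusted p = 0.101, and 0.0335 without DMSO replicate 2 and 0.0242 without CKBA replicate 1. It also passed by camera with the length trend removed (0.0346) or the GC trend removed (0.0248), in alternatives chosen after seeing the data. With an estimated correlation it passed in none of these 4 fits (adjusted p = 0.503, 0.561, 0.491 and 0.47). These counts depended on the libraries. Without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 and CKBA replicate 2, the rising genes were 0, 0, 1 and 0 for interferon, 1, 1, 1 and 2 for NF-κB, 1, 1, 1 and 1 for p53 and apoptosis, 0, 1, 0 and 0 for NRF2, and 1, 0, 1 and 1 for heat shock. In the same order the falling genes were 0, 0, 0 and 0 for interferon, 2, 1, 1 and 1 for NF-κB, 1, 1, 1 and 1 for p53 and apoptosis, 0, 0, 1 and 0 for NRF2, and 0, 0, 0 and 0 for heat shock. Without CKBA replicate 3, 8 NF-κB, 5 NRF2 and 4 heat shock genes rose and 1 apoptosis gene fell. Without DMSO replicate 3, 1 heat shock gene rose and 4 NRF2 targets fell, and with the block 2 heat shock genes fell. The NRF2 median, close to 0, ran from -0.05 without DMSO replicate 3 to 0.08 without CKBA replicate 3. With replicates 1 and 2 summed, 1 mitochondrially encoded gene fell, and 0 interferon, NF-κB, apoptosis, NRF2 or heat shock genes passed. Near-identical nuclear copies can share reads with mitochondrial genes, so these values are uncertain.

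Markers of B cells set CKBA replicate 3 apart. The B cell genes averaged 1.20 and 1.22 in CKBA replicates 1 and 2 and -0.96 in CKBA replicate 3, relative to the mean of the DMSO group on the log2 scale. Of 12 B cell genes, Fcer2a and Ms4a1 rose and 0 fell, also when adjusted over the list alone, with adjusted p of 0.032 and 0.0434, and 0.162 and 0.0913 with the replicate block (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fcer2a stood at 10.5, 9.75 and 0.781 CPM in CKBA replicates 1, 2 and 3, and at 0.895 CPM in DMSO replicate 3. Ms4a1 stood at 4.74, 5.07 and 1.21 CPM, and at 1.27 CPM in DMSO replicate 3. Neither gene was higher in CKBA replicate 3 than in DMSO replicate 3. Camera gave the list an adjusted p = 0.283, and 8.59e-05 without CKBA replicate 3, where the adjusted p = 0.112 with an estimated correlation. The Fcer2a and Ms4a1 calls were lost without DMSO replicate 1, DMSO replicate 2, CKBA replicate 1 or CKBA replicate 2, with adjusted p of up to 0.138 and 0.164 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 7 members rose without CKBA replicate 3. Myeloid genes lay lower in replicate 3 of both groups, at 0.20, 0.19 and -0.39 in DMSO replicates 1, 2 and 3 and 0.45, 0.40 and -0.42 in CKBA replicates 1, 2 and 3 on the same scale. Of 10 myeloid genes, 0 passed edgeR's test (0 adjusted over the list alone, camera adjusted p = 0.659), though 3, Cd74 among them, rose without CKBA replicate 3, and 1 fell without DMSO replicate 3 and with the block, with Cd74 at 53.0 ± 14.6 CPM with DMSO and 92.7 ± 52.5 CPM with CKBA. Of 6 keratinocyte genes, 0 passed edgeR's test and 2 were higher adjusted over the list alone (camera adjusted p = 0.19), though 1 fell without DMSO replicate 3 and 1 rose without CKBA replicate 3. Sfn stood at 32.2 ± 6.86 CPM with DMSO and 22 ± 4.98 CPM with CKBA and did not pass the test (adjusted p = 0.11). Sfn passed with the replicate block (0.00281, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and in 1 of the 6 fits without 1 library. Of the lists too small to test, 1 erythroid, 2 fibroblast and 4 histone genes were measured and 0 passed edgeR's test over all genes or adjusted over the list alone, with Fbln1 past it only with the block. The erythroid gene Alas2 stood at 0.19 ± 0.48, Thy1 of the fibroblast list at 0.17 ± 0.07 and the histone gene Hist1h1c at 0.12 ± 0.36 on the log2 scale. Thy1 had 671.5 CPM with DMSO and 753.5 CPM with CKBA. At such a level in T cell cultures it does not mark fibroblasts here.

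The largest rises by the fixed rule were those of Aldh1l2, Nupr1, Wnt10b, Hrh3, Ccl1, Chac1, Il1a, Cth, Akr1c18 and Slc7a3, with log2 fold changes from 5.41 down to 3.62. Nupr1, a stress-induced nuclear protein gene, rose from 0.603 ± 0.702 to 23.6 ± 5.61 CPM and Wnt10b, a Wnt ligand gene, from 0.259 ± 0.115 to 9.79 ± 1.28 CPM. Chac1, a glutathione-degrading enzyme gene induced by ATF4, rose by 4.30 and Cth, which makes cysteine from cystathionine, by 3.78. Akr1c18 was called only without DMSO replicate 3 when 1 library was left out, with an adjusted p of up to 0.0724 otherwise, and the other 9 genes stayed past the threshold in all 6 such fits (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest falls were those of Ly6g, Peg10, Itga7, Enpp2, Atp6v0d2, Lgr4, Tgfb3, Rbpms2, H2-Q10 and Smtnl2. Ly6g stood at 63.2, 63.3 and 2.35 CPM in DMSO replicates 1, 2 and 3 and had no count in any CKBA library. By the DMSO mean of 42.98 CPM, it was at least 951-fold lower with CKBA, against a floor of 3 counts over the group. This bound leaves out the spread between the DMSO libraries. Lgr4, an R-spondin receptor gene, fell from 33.7 ± 12.4 to 1.34 ± 0.484 CPM and Atp6v0d2, a proton pump subunit gene, from 16.5 ± 8.24 to 0.639 ± 0.346 CPM. Lgr4, Atp6v0d2 and Rbpms2 stayed past the threshold whichever library was left out. Ly6g, H2-Q10 and Smtnl2 kept the call in 1 such fit, that without DMSO replicate 3, with adjusted p of up to 0.213, 0.122 and 0.12 otherwise. Peg10, Itga7 and Tgfb3 lost it without CKBA replicate 1, 2 or 3, with up to 0.0725, 0.0895 and 0.0615, and Enpp2 without those or DMSO replicate 2, with up to 0.1. Itga7, H2-Q10 and Smtnl2 did not pass with the replicate block (adjusted p of 0.0639, 0.0542 and 0.154, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). H2-Q10 belongs to a family of near-identical genes, so its value is uncertain.

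The remaining genes of the fixed rule moved less or were called in fewer fits. Higher with CKBA were Areg by 3.40, Slc7a11 by 2.04, Ptgs1 by 1.85, Hmox1 by 1.25, Lrrc32 by 0.82, Ifih1 by 0.82, Hspe1 by 0.65, Nfkbia by 0.41, Decr1 by 0.40, Hspd1 by 0.37, Tgfb1 by 0.37, Echs1 by 0.36, Txn1 by 0.35, Ccng1 by 0.34 and Etfa by 0.30 on the log2 scale. Lower were Il24 at -2.04, Gstm1 at -1.92, Gbp5 at -1.48, Irf7 at -1.15, Bcl2l11 at -1.11, Stat4 at -1.08, Ier3 at -0.98, Traf1 at -0.46, Bag3 at -0.45 and Eci2 at -0.42. Of these, Stat4 alone kept its call whichever library was left out. Without CKBA replicate 3 the rise of Areg was 2.18 and that of Hmox1 0.68. Srebf1 at -0.33, Perp at 0.36, Nr1h2 at -0.14, Cst3 at -0.04 and Hist1h3c at 0.82 (0.52 without DMSO replicate 3) did not pass the test. Srebf1 passed with the replicate block (adjusted p = 0.00705, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and in 1 of the 6 fits without 1 library. In those 6 fits it ran from -0.41 to -0.22, the latter without CKBA replicate 3.

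In the authors' deposited table, 860 genes were marked as changed, 304 higher and 556 lower, all with an absolute log2 fold change of at least 1. Of these, 773 were tested here and 659 passed, none in the opposite direction. The authors' deposited table listed 1628 more genes at an FDR under 0.05, with absolute log2 fold changes of up to 1.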

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

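The alternatives chosen after seeing the data were leaving out replicate 3 of both groups, a covariate for replicate 3, summing replicates 1 and 2, and removing length or GC trends. Of 1095 higher and 1286 lower genes, the counts stayed within 1.5 times under other size factors, other low-count filters, DESeq2, limma-voom, the edgeR exact test and the test on FPKM. They rose to 1922 and 2009 with the replicate block, 1928 and 2040 with the block and the length trend removed, 1843 and 1932 with the block and the GC trend removed, 2460 and 2487 with the covariate, and 3660 and 3728 without replicate 3 of both groups. They fell to 264 and 464 with a minimum fold, where 36.3% of calls were higher, and to 56 and 54 with replicates 1 and 2 summed. Leaving out 1 library gave 251 to 1961 higher and 390 to 2014 lower genes. The lowest counts came without DMSO replicate 2 and the highest without CKBA replicate 3. Of 2381 calls, 2315 stayed with the block, 110 with the sum and 637 without DMSO replicate 2, and 0 changed sign in any of these fits. Fewer samples and their uneven spacing enter the fits with a library left out or summed, and the cause of the other shifts was not tested. Of the 12 gene lists, 0 passed with an estimated correlation in camera (1, ribosomal proteins, without CKBA replicate 3) and 5 of 30 had an unadjusted p under 0.05. The estimated correlation was 0.0064 for TH17, -0.0054 for IL-6 and STAT3 and -0.0115 for CD8 and NK genes, all below the preset 0.01. For ribosomal protein, cell cycle, glycolysis and oxidative phosphorylation genes it was 0.55, 0.74, 0.67 and 0.70. Fry called 12 of 30 lists, not the same ones: glycolysis (adjusted p = 0.148), hypoxia (0.317), oxidative phosphorylation (0.353) and activation (0.0669) were lost, and apoptosis (0.00742), LXR targets (0.0334), keratinocyte (0.0334) and NF-κB (0.0422) gained. By camera, activation was lost with upper-quartile factors (0.0551), the stricter filter (0.125) and FPKM (0.111). Without a low-count filter the CD8 and NK list was lost (0.22), and apoptosis (0.0335) and mitochondrially encoded genes (0.0425) gained. With the block, the mitochondrial list was gained when the length (0.0495) or GC trend (0.0343) was removed, and NF-κB with the GC trend removed (0.0259). B cell (4.1e-05) and interferon (0.027) lists were gained without replicate 3 of both groups. Of these gained calls by camera with a preset correlation, none refitted with an estimated correlation passed, the lowest adjusted p being 0.204. The losses of oxidative phosphorylation, IL-6 and STAT3 and hypoxia are given with those lists. Leaving out 1 library left 10 to 13 lists. Among named genes, Il22 turned to -0.40 with the block, -1.12 with limma-voom and -2.60 without replicate 3 of both groups, where it passed, and ran from -3.72 to 1.65 with 1 library left out. The cause was not tested. Srebf2 turned to -0.0184 with the sum. With 1 library left out, Srebf2 ran from -0.0357 to 0.104, Cst3 from -0.135 to 0.0687, Hist1h1c from -0.14 to 0.41 and Alas2 from -0.12 to 0.52, all uncalled. The block ended 14 of 117 named calls and changed no call of a list. No change below about 1.5-fold is well covered at this depth and n, since 22 of 50 simulated genes of that size were called. The simulated changes lay in genes of at least 5 CPM, so less abundant genes may be covered less well.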

Other observations

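The gene groups in these first paragraphs were chosen after the results were seen, so their tests describe and do not decide. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher with CKBA: of 20 genes 12 rose and 0 fell, with a median log2 fold change of 0.63 (camera adjusted p = 4.08e-10 over 8 such groups, adjusted p = 0.127 with an estimated correlation). Cars rose by 1.35 ± 0.08, Nars by 1.02 ± 0.09 and Yars by 0.99 ± 0.08 on the log2 scale. Of 17 mitochondrial synthetases, Rars2 rose and 0 fell, with a median of 0.07 (camera adjusted p = 0.214), and 4 rose with the replicate block. The mean of the cytosolic group was higher by 0.46, with a permutation p of 0.00026 across genes, which are not independent replicates. Of 23 amino acid transporters 9 rose and 1 fell (camera adjusted p = 4.79e-04, adjusted p = 0.0957 with an estimated correlation). Slc7a1, a cationic amino acid transporter, rose by 1.01 ± 0.08 and Slc7a11, the cystine transporter, by 2.04 ± 0.42.

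Genes of lymphocyte homing and antigen presentation also moved. Of 8 Gimap genes, GTPases of lymphocyte survival, 5 fell and 0 rose, with Gimap4 at -1.41 ± 0.09 (camera adjusted p = 9.45e-06, adjusted p = 0.0651 with an estimated correlation). Of 15 chemokine receptors 8 fell and 2 rose, with Cxcr1 at -3.60 ± 0.40 and Cx3cr1 at 2.27 ± 0.27 (camera adjusted p = 0.0168, adjusted p = 0.0957 with an estimated correlation). Of 14 chemokines 6 rose and 0 fell, with Xcl1 at 2.56 ± 0.27 and Ccl22 at 2.10 ± 0.21 (camera adjusted p = 9.96e-04, adjusted p = 0.088 with an estimated correlation). Of 18 class I antigen presentation genes 10 rose and 2 fell, with H2-K1 at 0.85 ± 0.08 and B2m at 0.83 ± 0.09 (camera adjusted p = 9.13e-05, adjusted p = 0.0883 with an estimated correlation). Values of the H2-Q and H2-T genes are uncertain, since these near-identical genes share reads. Of 42 proteasome genes 3 rose and 0 fell, and 8 rose with the replicate block (camera adjusted p = 0.00799, adjusted p = 0.565 with an estimated correlation). Ly6g, a neutrophil marker, was high in DMSO replicates 1 and 2, while S100a8, S100a9, Mpo, Elane and Camp together had 5 counts in the DMSO libraries and 12 in the CKBA libraries.

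Of the tests that follow, the splits of the libraries were planned before and all others were chosen after the results were seen. Of 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes past the threshold as the real split, which was the real split itself with 2381, against 0 for the highest other, and 4560 against 1174 genes at an unadjusted p under 0.05. For the gene lists it was also 1 of 10, with 12 lists in the real split and 9 in the highest other. So few splits cannot tell chance from treatment.

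Glycolysis and hypoxia genes were lower with CKBA in the comparison of groups, but in DMSO replicate 3 they were as low as in the CKBA libraries. If that library held RNA of a CKBA culture, its stress response genes would be high too. They lay at 3.83% of the way from DMSO replicates 1 and 2 to the CKBA libraries, which argues against a library made wholly of such RNA. Ribosomal protein, naive and memory, IL-6 and STAT3, and oxidative phosphorylation genes lay at 0.952%, -3.82%, -35.7% and -47.8%. TH17 genes lay at 16.05%, serine and one-carbon genes at 18.1%, CD8 and NK markers at 34.9%, cell cycle genes at 40.3% and activation genes at 55.3%. Glycolysis and hypoxia genes themselves lay at 88.25% and 111.7%. A mix that brought them there would also have moved the stress response and ribosomal protein genes most of the way. Their values therefore argue against a mix as the cause of the low glycolysis and hypoxia genes. A smaller mix is not excluded. Within replicate pair 3 the glycolysis genes differed by 0.043 on the log2 scale, against -1.08 and -1.19 in the other pairs. The hypoxia genes differed by 0.35, against -1.31 and -1.47, so within pair 3 they were higher with CKBA. A culture difference carried by the replicate number, such as density or harvest time, would cancel within a pair if it moved both libraries alike. The differences within pairs therefore cannot show such a shift. In glycolysis genes, DMSO replicate 3 lay at -0.93 from the other DMSO libraries, and CKBA replicate 3 at 0.25 from the other CKBA libraries. In hypoxia genes they lay at -1.44 and 0.29. A shift that moved both libraries alike would give the same sign in both groups. For these genes the values argue against it, though each rests on a single library. As a hypothesis, an effect of CKBA on glycolysis may depend on the state of the culture, and new cultures matched for density would test it.

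Ribosomal protein genes were higher by a small, even amount, and their transcripts are short, with a median of 712 bases against 1331 over all tested genes. With each library's trend over transcript length removed, the median of the list was 0.43, and with the GC trend removed 0.49, which argues against either bias as the whole cause. Sharing of reads with processed pseudogenes was not tested. A biological explanation, such as a larger output of the translation machinery, is a hypothesis that was not tested.

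Markers of CD8 T cells and NK cells were lower with CKBA. A smaller share of such cells would lower the effector genes and the other markers alike. The mean log2 fold change of 2 effector genes minus that of the other 6 tested genes of the list was -1.37 ± 0.23, but this cannot tell. The effector genes were picked after their values were seen, and the receptor gene Klrd1 fell about as far as the effector gene Prf1 (-1.25 and -1.35). Of the other genes, Tyrobp and Klra7 stood at only 0.56 and 4.21 CPM with DMSO. The cultures were started from naive CD4+ T cells, a selection that should leave few CD8 T cells or NK cells, but the labels do not state its purity. A smaller share of remaining CD8 T cells or NK cells and lower expression within the CD4+ cells both stay open, and counting these cells in new cultures would test the first.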
